A study of Homo sapiens with 6 samples.

How the data were processed

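MicroRNA levels were measured in JJ012 cells, a human chondrosarcoma line, by quantitative PCR. Per the labels, 3 samples had received PRP-1, a cytokine described as an inhibitor of the growth-regulating kinase complex mTORC1, and 3 samples were controls. Per the labels' protocols, 5000000 cells were seeded per dish, dishes were kept for 24 hours at 37 °C under 5% CO2 before PRP-1 was added, and for each panel 20 ng of RNA was polyadenylated and copied into cDNA, then amplified on ready-made locked-nucleic-acid PCR panels with SYBR Green. The dose of PRP-1, the time between its addition and lysis, and the instrument and software settings are not given in the sources used here. The labels do not say whether the samples of a group came from separate cultures.

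All values reported here come from the authors' deposited table of fold changes. Per the file headers, the authors computed each fold as 2 to the power of minus the difference in ΔCt, PRP-1 (test) over control, where Ct is the PCR cycle at which an assay crosses its threshold and ΔCt is Ct relative to a reference. The reference, the limit of detection, the treatment of missing values and any filter are not given in the sources used here. The deposited values are signed folds. A value above 0 is the ratio itself, and no value lay between -1 and 1 (the smallest size was 1.00), so a negative value was read as the reciprocal of a ratio under 1. The table gives 1 fold per row for the whole comparison, with no value per sample, no error and no p-value. It holds 220 rows for 217 assay names, because 3 assays have 2 rows each.

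A companion table of raw Ct lists 742 assay names. Its 6 value columns carry names that match no label of any sample. Neither column order nor the values were used to assign them to samples or groups, so no value from those 6 columns was used. The tests planned before the data were examined needed values per sample. These were a moderated test with limma on normalised Ct for assays with a Ct under 37, counts of detected assays, set tests and leaving out each sample, and none of them was run. Of that table only the assay names were used, together with the fact that some rows hold no value in any column. This was so for 376 of its 742 assays and for 57 of the 217 assays with a deposited fold. No Ct could be set beside those 57 folds, and this is said where such an assay is named. An assay is said to have a Ct if any of those columns holds a value for it, and the filled columns per row were not counted. Since no value of those columns was used, the amount of each miRNA and the spread between samples are not known here. No test between groups and no error of a fold is therefore given here. The doubling of product per cycle that a fold from Ct assumes was not checked.

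Folds were put on the log2 scale with falls negative, and the rows of a repeated assay were averaged there. The only measure of repeatability in the table is the difference between rows of the same assay, and it comes from 3 assays. A fold of 2 in either direction was used to describe sizes. This threshold, the averaging of repeats and all alternatives were chosen after the table had been seen. The 17 miRNA lists, with their members, were fixed before the data were examined, and an assay belonged to a list by its name alone. Names ending in a star were never counted as members. For each of the 13 lists with at least 3 members in the table, the median log2 fold was set among the medians of 10000 random lists of the same size drawn from the 217 assays, with 95% ranges. The random lists were not matched on abundance, since no value of the raw table was used. These percentiles describe the table and are not tests across samples.

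The assays named are those fixed by rule beforehand, as far as the rule could be applied. They are the 4 largest folds in each direction in the deposited table and up to 4 members of each list with the largest folds. The parts of the rule that needed a test, or detection per sample, could not be applied. Other assays named in the text were chosen after their values were seen.

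The spacing of the log2 folds was examined as a check on how they were made. Each was divided into steps of 1/300 cycle, the spacing that a mean of 3 values given to 2 decimals would have, and classed by its remainder with a tolerance of 0.01 step. In simulated data with known classes for 220 rows, 100% of the values were given their class, and 8.2% of values drawn without a grid fell in any class. In the same simulation of 220 rows, 2 of 100 lists of 10 members that had not been moved, 38 of 100 lists moved by 0.5 on the log2 scale and 84 of 100 moved by 1 lay above the 95% range of random lists. Lists of other sizes and lists moved downwards were not simulated. Neighbouring miRNA genes were found through NCBI RefSeq's gene table (GRCh38.p14), used for gene names and neighbourhood only. Of 179 assays without a star in their name, 137 matched a single gene. The deposited table names no genome build, so no coordinates are given. Python 3.11.15, NumPy 2.4.6 and Matplotlib 3.10.9 were used.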

Results

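The study asked which miRNAs, and in particular which oncogenic and tumour-suppressor miRNAs, differ in JJ012 chondrosarcoma cells after PRP-1. It compared 3 PRP-1 samples with 3 control samples on quantitative PCR panels of miRNA assays. MiRNAs are short RNAs that repress messenger RNAs. A name ending in a star denotes the usually less abundant arm of a precursor hairpin. All folds are the authors' values for the whole comparison, with no error and no replicate check here. Sequencing depth does not apply to PCR, and the Ct behind each fold was not used, so abundance is unknown.

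In the authors' deposited table, 121 of 217 assays were listed higher with PRP-1 and 96 lower. At least 2-fold differences were listed for 37 assays upwards and 33 downwards, relative to the authors' reference, and at least 4-fold differences for 7 upwards and 15 downwards. The largest values in the authors' deposited table were reductions: miR-509-3p was listed 12.9-fold lower, miR-589 7.46-fold lower, miR-495 7.04-fold lower and miR-490-3p 6.73-fold lower. The largest increases in the authors' deposited table were 5.58-fold for miR-324-5p, 5.29-fold for miR-20a*, 4.87-fold for miR-125b-1* and 4.52-fold for miR-29b, a miRNA known to target collagen messenger RNAs. The raw table holds no Ct for miR-20a* or miR-125b-1*, so their folds have no measurement beside them. Of these 8 assays, miR-589 alone lay on the grid of evenly spaced values that 148 of the 220 folds share.

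The median log2 fold in the authors' deposited table was 0.19, or 1.14-fold, with quartiles of -0.50 and 0.81. Directions are relative to the authors' reference, which is not stated. With the table's own median as zero, at least 2-fold differences numbered 25 upwards and 36 downwards, so the balance of these assays turned. It also turned among the 145 assays on the common grid, with 12 upwards and 14 downwards, and among the 160 with any Ct in the raw table, with 21 upwards and 29 downwards, and among the 179 without a star in their name, with 26 upwards and 29 downwards. The assays measured in 2 rows of the authors' deposited table give the only view of repeatability. MiR-103 was listed 1.67-fold and 1.73-fold higher, miR-191 1.29-fold and 1.02-fold lower, and miR-423-5p 1.25-fold and 1.13-fold lower. The widest of these 3 gaps was 0.35 on the log2 scale, or 1.27-fold. Folds of 53 assays were within that gap of no difference, 101 were higher by more than it and 63 lower by more. All 6 of these repeat rows were on the common grid and had a Ct beside them. No repeat therefore bears on the off-grid folds or on folds without a Ct. Whether the gap holds for assays of other abundance is not known. A gap between rows of one comparison says nothing of the spread between cultures.

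**Figure D1:**
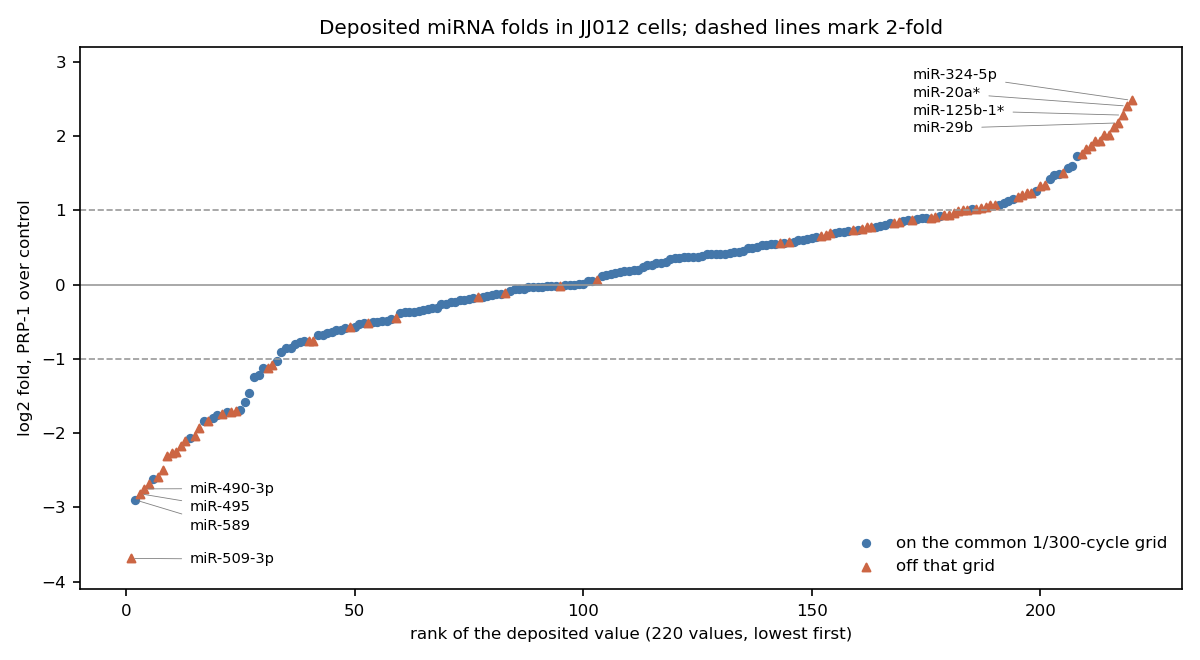
Log2 fold (PRP-1 over control) of the 220 deposited values in order of size, with rank on the horizontal axis; circles are values on the grid of 1/300 cycle that most values share, triangles are values off it, and dashed lines mark 2-fold. Of the 72 triangles, 44 lie at or beyond the dashed lines, and the lowest value is that of miR-509-3p, 12.9-fold lower.

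Among miRNAs that the literature calls oncogenic, 17 of 22 fixed members had a fold, 12 of them above control and 5 below. In the authors' deposited table, miR-21, an abundant miRNA of many tumours, was listed 2.22-fold higher, miR-19b 3.34-fold higher and miR-20a 2.19-fold higher, while miR-135b was listed 4.30-fold lower. The remaining members were listed at less than 2-fold, apart from miR-18a at 2.11-fold higher. The median of this list in the authors' deposited table was 0.38 on the log2 scale, at percentile 70.2 of random lists. The folds of miR-135b and miR-96 were off the common grid, and those of 6 of the 17 members were within the widest gap between repeated rows.

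Among miRNAs that the literature calls tumour suppressors, 26 of 41 fixed members had a fold, with 17 above control and 9 below. At least 2-fold increases were listed in the authors' deposited table for miR-29b (4.52-fold), miR-192 (4.05-fold), miR-101 (2.98-fold) and miR-15a (2.79-fold), and no member was listed at 2-fold lower or beyond. The folds of miR-29b and miR-192 were off the common grid, and those of miR-101 and miR-15a on it. Folds of 7 of the 26 members were within the widest gap between repeated rows. MiR-192 is known as a p53-responsive miRNA, miR-101 as a repressor of the histone methyltransferase EZH2 and miR-15a as a repressor of the survival factor BCL2. The median log2 fold of the list in the authors' deposited table was 0.46, at percentile 88.0 of random lists. The difference between these medians, oncogenic minus tumour-suppressor, was -0.08. Reassigning the 43 assays to lists of these sizes at random gave differences from -0.51 to 0.42 in 95% of draws, so the lists were not told apart in this table.

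Families and clusters differed in how evenly their members were listed. In the authors' deposited table all 5 members of the miR-232724 clusters were above control, from 1.31-fold for miR-23b to 2.02-fold for miR-27b, with miR-27a at 1.85-fold and miR-24 at 1.66-fold. All 3 members of the miR-29 family were also above control in the authors' deposited table, at 4.52-fold for miR-29b, 1.86-fold for miR-29a and 1.15-fold for miR-29c, the last within the widest gap between repeated rows. The miR-17~92 cluster and its paralogs, which MYC is known to activate, had 7 of 10 assays above control, with miR-106a listed 1.80-fold higher in the authors' deposited table beside miR-19b, miR-20a and miR-18a. The other 3 members, miR-17, miR-19a and miR-92a, were listed 1.27-fold, 1.25-fold and 1.42-fold lower in the authors' deposited table. The folds of miR-17, miR-19a and miR-18b, 3 of the 10, were within the widest gap between repeated rows. Medians of these lists were 0.73, 0.90 and 0.55 on the log2 scale, at percentiles 86.1, 88.9 and 84.4 of random lists, all inside the 95% range. That range is wide for short lists, from -1.72 to 1.26 for the 3 miR-29 members, so lying inside it excludes little.

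The let-7 family, whose members repress RAS and MYC messenger RNAs, was listed in both directions. The authors' deposited table had let-7f 1.55-fold, let-7g 1.49-fold and let-7i 1.35-fold higher, let-7a 1.60-fold lower, and let-7b, let-7c, let-7d and let-7e between 1.11-fold and 1.29-fold lower. Its median log2 fold was -0.17 in the authors' deposited table, at percentile 17.9 of random lists. The folds of 3 of the 8 members, let-7c, let-7d and let-7e, were within the widest gap between repeated rows. Family members differ by a few bases, and cross-reaction between their assays was not checked. Of the miR-30 family, the authors' deposited table had miR-30b 1.75-fold and miR-30c 1.46-fold higher and miR-30a 1.69-fold lower, with a median of 0.55 at percentile 71.0. The fold of miR-30a was off the common grid.

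The list most displaced was the imprinted miRNA cluster at 14q32. In the authors' deposited table, miR-495 was listed 7.04-fold, miR-381 4.17-fold, miR-134 3.22-fold and miR-665 2.74-fold lower, while miR-485-3p was listed 1.91-fold and miR-412 1.46-fold higher. The median of the 6 members in the authors' deposited table was -1.57 on the log2 scale, at percentile 0.26 of random lists of 6, whose 95% range ran from -0.88 to 0.97. With any 1 member left out the median stayed between -1.69 and -1.45. Leaving out 1 of 6 always returns a middle value, here that of miR-134 or miR-665, so this says nothing of the other members. The 14q32 list was the 1 list of 13 outside its 95% range. The percentile was not corrected for the number of lists, and with 13 lists 1 can fall outside by chance. The list had 46 members on the panels, so most had no fold in the table. The raw table holds no Ct for miR-412 or miR-485-3p, and the folds of miR-495 and miR-485-3p were off the common grid. The primate-specific miRNA cluster of chromosome 19 had 4 members in the authors' deposited table, with miR-523 listed 3.28-fold lower, miR-520d-3p 2.32-fold higher, miR-526b 1.78-fold higher and miR-520h 1.08-fold lower. Its median was 0.36 at percentile 62.7, and all 4 folds were off the common grid. No Ct stands beside miR-520d-3p or miR-520h.

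Cartilage miRNAs went both ways. In the authors' deposited table the arms of the cartilage-specific miR-140 hairpin were listed 1.89-fold higher for miR-140-5p and 1.70-fold lower for miR-140-3p. MiR-27b was listed 2.02-fold and miR-455-5p 1.92-fold higher in the authors' deposited table, and miR-199a-5p 5.66-fold lower. The remaining members there were miR-455-3p, 1.28-fold higher with no Ct beside it, and miR-145, 1.02-fold lower. The list median in the authors' deposited table was 0.35, at percentile 57.7 of random lists, and the folds of miR-199a-5p and miR-455-5p were off the common grid. Among miRNAs reported to target MTOR or its complex, the authors' deposited table had miR-101 2.98-fold, miR-99a 1.45-fold and miR-100 1.40-fold higher and miR-99b 1.53-fold lower, with a median of 0.51 at percentile 73.9. Of 6 p53-responsive miRNAs, 3 were above and 3 below control in the authors' deposited table, with miR-192 at 4.05-fold higher, miR-15a at 2.79-fold higher, miR-107 at 1.42-fold higher and miR-605, which is off the common grid and has no Ct beside it, at 3.26-fold lower. The other members below control, miR-16 at 1.20-fold and miR-145 at 1.02-fold lower in the authors' deposited table, were within the widest gap between repeated rows. The median of these 6 was 0.24 on the log2 scale, at percentile 53.8, and 0.51 without miR-605.

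Listed markers of other cell types were nearly missing from the fold table. No listed marker of blood, of muscle, or of liver and pluripotent cells had a fold. The raw table does name an assay for every member of these lists. Star-named arms were not counted as markers. In the authors' deposited table miR-302c*, named after the listed miR-302c, was 6.46-fold lower and off the common grid. MiR-141*, named after the listed epithelial marker miR-141, was 1.20-fold lower, with no Ct beside it. Among listed epithelial markers the authors' deposited table held miR-200c alone, a repressor of the transcription factor ZEB1, at 2.53-fold higher. Among neuron markers the authors' deposited table had miR-9 2.17-fold lower, miR-128 2.04-fold lower and miR-138 1.63-fold higher, with a median of -1.03 at percentile 5.96 of random lists of 3. Folds of miR-200c and miR-9 were off the common grid. A missing fold was not read as a missing miRNA, because the authors' criterion for listing an assay is not given in the sources used here.

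**Figure D2:**
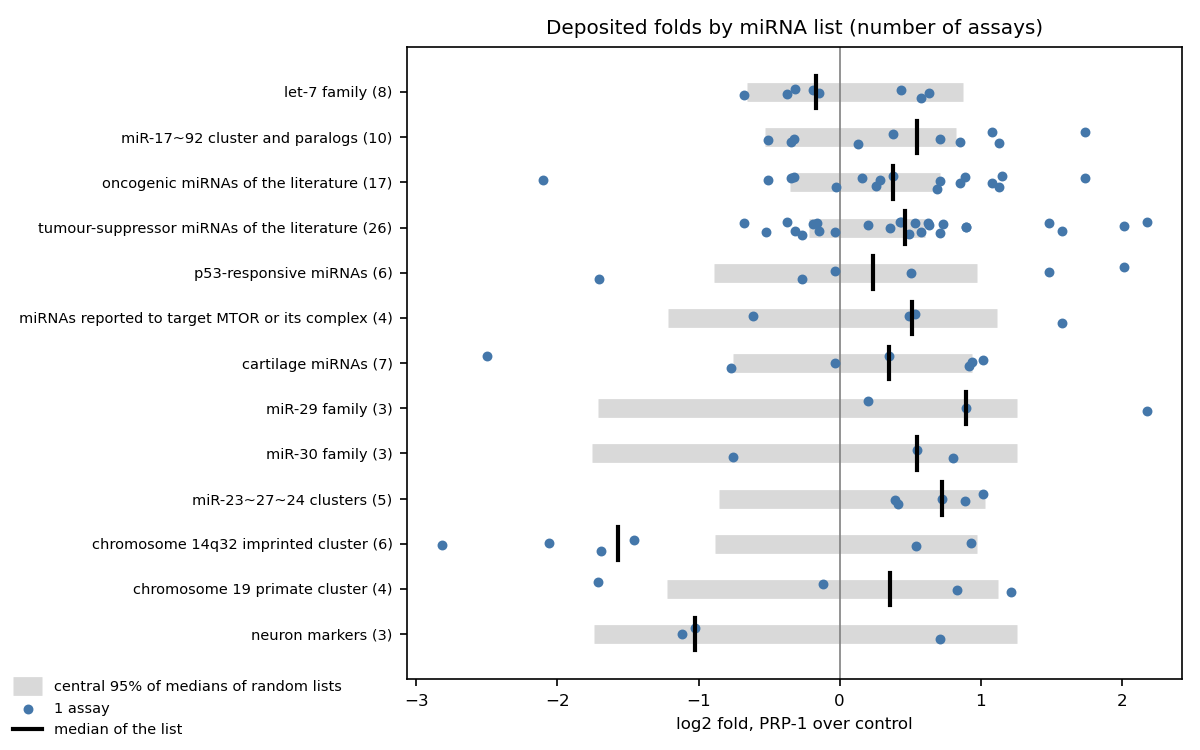
Log2 fold (PRP-1 over control, horizontal axis) of each assay of the 13 miRNA lists with at least 3 members in the deposited table, with the number of assays in brackets; points are assays, black bars are list medians and grey bands hold 95% of the medians of random lists of that size. The median of the 14q32 cluster, -1.57, is the one outside its band.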

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

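All alternatives here were chosen after the table had been seen. None of the planned ones on normalisation of Ct, detection limits, the test or the replicates was run, because each needs Ct values assigned to samples, and no paired analysis was possible because the per-sample columns carry no sample's label. Taking the first or the second row of each repeated assay changed no count by direction or at 2-fold and no list median. It could not have, since the repeats agree in direction, lie under 2-fold and are in no list. The counts by the widest gap between repeated rows were not recomputed and do depend on this choice. The first row of miR-191, at -0.37 on the log2 scale, lies beyond that gap, and the mean of its rows within it. Centring on the table's median moves every fold alike. It left 25 assays at least 2-fold higher (from 37) and 36 at least 2-fold lower (from 33), so that 41.0% of the 2-fold assays were higher, against 52.9%. With the 145 assays on the common grid, 76 were listed higher (from 121), 12 at least 2-fold higher, which is 8.3% of the assays kept against 17.1%, and 14 at least 2-fold lower, which is 9.7% against 15.2%. The lower shares at 2-fold go with the larger folds of the assays removed. With the 160 assays that have any Ct in the raw table, 21 were at least 2-fold higher, or 13.1%, and 29 at least 2-fold lower, or 18.1%. The share listed higher was 55.8% in the authors' deposited table, 52.4% on the common grid, 53.1% with a Ct and 55.9% without star-named assays. Restriction to the grid or to assays with a Ct removed members from some lists. Of the list medians affected, 8 could be recomputed, and these kept their sign and moved by at most 0.30 on the log2 scale, while 5 were left with fewer than 3 members. The spread between samples was not measured here, so how far it limits these values is not known.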

Other observations

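The tests in this part were chosen after the folds had been seen. Star-named arms made up 38 of the 217 assays, and 21 of them were listed higher in the authors' deposited table. Several exceeded their partner by name: miR-17* was listed 3.40-fold higher in the authors' deposited table against miR-17 at 1.27-fold lower, and miR-16-2* 4.34-fold higher against miR-16 at 1.20-fold lower. The name miR-16 carries no copy number, so it need not come from the hairpin of miR-16-2* alone. The opposite was listed for miR-181a*, 4.96-fold lower in the authors' deposited table against miR-181a at 1.33-fold higher, and for miR-30b*, 2.33-fold lower against miR-30b at 1.75-fold higher. No Ct stands in the raw table beside 27 of the 38 star-named folds, miR-17* and miR-16-2* among them. The folds of miR-17*, miR-16-2* and miR-181a* were off the common grid.

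A candidate expectation is that arms cut from one hairpin share its transcription and so have similar folds. Matching by name gave 42 pairs, in which let-7a, let-7f and miR-181a each occur repeatedly. Where a star name carries a copy number, as in miR-125b-1*, its partner's name carries none and need not come from that hairpin alone. Over these 42 pairs, arms had the same direction in 21. Their median gap was 0.74 on the log2 scale, at percentile 40.6 of the medians that random pairing of the same arms gave, and 35 pairs differed by more than the widest gap between repeated rows, a gap known for on-grid folds only. The median gap was 0.62 for the 21 pairs with both arms on the common grid, 9 of them in the same direction, and 1.22 for the other 21, with 12 in the same direction. Neighbouring miRNA genes within 10 kb gave the same picture, with 21 of 40 pairs in the same direction and a median gap of 0.95 against 0.60 to 1.26 for shuffled folds. These 40 pairs were formed from 42 assays and are not separate gene pairs. For example, miR-500a was paired with both arms of miR-501, miR-502 and miR-532. MiR-221 and miR-222, 1.20-fold and 1.22-fold higher in the authors' deposited table, lay close together, and miR-424 and miR-542-5p, 2.82-fold higher and 3.28-fold lower, lay far apart. With no error per fold, separate processing of arms cannot be told apart from measurement noise.

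The log2 folds are not evenly fine. Of 220 rows, 148 left the same remainder on a grid of 1/300 cycle, and the other 72 lay 0.25, 0.5 or 0.75 step from it (32, 17 and 23 rows), with none elsewhere at a tolerance of 0.01 step. Rows off the common grid had a median absolute log2 fold of 1.15 against 0.49 on it. The difference of 0.66 exceeded the range of -0.21 to 0.22 from random reassignment, and 19 of the 22 rows at 4-fold or more were off the grid, as were 44 of the 70 at 2-fold or more. One hypothesis is that off-grid folds rest on fewer samples or on substituted values and are noisier. The difference of 0.66 prompted this hypothesis and cannot test it. For values given to 2 decimals, fewer Ct with an unchanged reference would move a fold by 0.5 step or not at all. With the reference unchanged, fewer samples would then not give the 32 and 23 rows at 0.25 and 0.75 step. If a sample without a Ct also dropped out of the reference, the offsets would set no such limit. The reference is not stated, so the offsets do not decide on fewer samples. Substituted values and a changed reference were not tested, and the empty columns per row of the raw table were not counted. The assays with no Ct in the raw table do not account for the difference of 0.66. Among rows with a Ct it was 1.01, beyond a random range of -0.24 to 0.23. Of the 57 rows with no Ct, 31 were off the grid and the others on it. Lying on the grid therefore does not show that a fold has a Ct beside it. A real difference after PRP-1 that left some samples of one group without a Ct would give a difference of the same sign. It stays open and untested beside the first, and the offsets do not decide on it either.

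Assays with no Ct in the raw table were listed higher in 36 of 57 cases in the authors' deposited table, with a median log2 fold of 0.55, against 85 of 160 and 0.09 for the others. Folds equal to all 6 printed digits were carried by 27 rows in the authors' deposited table. This was within the 16 to 40 rows found when each fold was moved at random by up to 30 grid steps. Among the 27 rows were miR-192 with miR-196b at 4.05-fold higher. Also among them were let-7f-1* with let-7f-2* at 2.10-fold higher, the let-7 pair with no Ct beside it. Both pairs were off the common grid. The random range counts all rows together, so it does not bear on these pairs. MiR-300, which lies beside miR-381 and miR-495 but was not on the fixed 14q32 list, was listed 1.43-fold lower in the authors' deposited table, also with no Ct beside it.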
